A study of Mus musculus with 30 samples.

How the data were processed

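The series compared mouse embryonic stem (ES) cells that carry floxed alleles of Tdg (fl/fl), the gene of thymine DNA glycosylase, with ES cells in which Tdg was deleted (Tdg -/-). Thymine DNA glycosylase excises 5-formylcytosine (5fC) and 5-carboxylcytosine, which TET enzymes make from 5-methylcytosine by way of 5-hydroxymethylcytosine (5hmC). The labels list 30 libraries. The region lists come from 18 of them: 2 libraries each of DNA enriched for 5fC and for 5hmC from fl/fl ES cells, Tdg -/- ES cells and fl/fl embryoid bodies (EB) at day 5, and 3 libraries of p300 chromatin immunoprecipitation for each ES genotype. Another 4 libraries hold polyA RNA, 2 for each genotype, read at 51 bp. The enriched DNA libraries were amplified for 18 PCR cycles, per the labels' protocols. The remaining 8 libraries were not analysed here: 2 of input DNA, 2 control enrichments without the NaBH4 treatment, and 4 of H3K4me1 chromatin after bisulfite or fCAB treatment.

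The authors deposited 8 region lists, 1 for each mark and group, and per the labels each list covers all replicates of its group together. The score of each region, deposited by the authors, is minus 10 times the log10 of a p-value per the file headers of the ES 5fC and 5hmC lists, and the lists without a header were read on the same scale. Such a score grows with library depth, so it was used only to rank or filter regions within a list. Bowtie and MACS 1.4 are named in the submitters' processing notes, with the mm9 genome build, and the threshold of the calls is not given in the sources used here. The lowest score was 60.92 in the fl/fl ES 5fC list and 50 in the other 7 lists, so the first of these was filtered more strictly. Starts and ends are printed as deposited, and whether the starts count from 0 or from 1 is not given in the sources used here.

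Expression was read from 2 tables of FPKM, deposited by the authors, with 1 value for each gene symbol and genotype. TopHat 1.4.1 and Cufflinks 1.3.0 are named in the submitters' processing notes, and how the replicates were combined is not given in the sources used here. Each table had 20437 rows for 20286 symbols, and rows with the same symbol were summed. Neither the lists nor the tables give read numbers, so the sequencing depth behind each list and each FPKM value is unknown.

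Since each group has 1 pooled list or value, no spread between replicates can be had, and no test here compares replicates. Regions on chromosomes 1 to 19 and X were used. A region was called kept where it shared at least 1 bp with a region of the other list, gained where it was in the Tdg -/- or EB list alone, and lost where it was in the fl/fl ES list alone. Shares are given with Wilson 95% confidence intervals, which cover counting error only. Whether regions of 1 list overlapped another more often than chance was tested against 1000 circular shifts of the first list along each chromosome, from 3 Mb to its last region, one-sided, with 1e-03 as the smallest p the shifts can give. Fold values over the shifts carry the SD of the shifts. Classes of regions were compared by the difference of their overlap shares on each of the 20 chromosomes. The printed difference is the mean over chromosomes, each counted once, with the SE over chromosomes. The shares printed beside it are pooled over all regions, so they need not differ by the same value. The test was a two-sided sign-flip permutation test of 100000 resamples, whose smallest p is 1e-05. Both tests ask about position in the genome in these lists. Chromosomes are not biological replicates and the threshold was 0.05. P-values are printed unadjusted. Over the family of 11 tests, the 10 that passed also passed after Benjamini-Hochberg adjustment, with a largest adjusted p of 0.0011.

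Changes in expression are log2((Tdg -/- FPKM + 1)/(fl/fl FPKM + 1)), which understates the change of genes at low levels. Genes with an FPKM of at least 1 in either genotype were measured, and those with a log2 change of at least 1 in either direction were counted, with no p-value. Of each of 18 gene lists, the median change was set against 10000 random lists of the same size matched on mean expression, and its percentile describes these pooled values only. A 95% bootstrap interval of each list median, from 2000 resamples of its measured members, served only to judge how far the median moved under the alternatives. The genes named are Tdg, the 12 with the largest rise and the 12 with the largest fall among those with an FPKM of at least 5 in either genotype, and up to 4 members of each list with the largest absolute change, with any member changed by at least 1; the values of 1 gene within this rule are not reported here. Of each class of gained or lost regions, the 3 with the highest scores could be named. Regions of the genome prone to false signal were not removed here, so the named ones may include such regions. The tests, lists, naming rule and most alternatives were fixed before the data were examined. Chromosomes of genes and their order were taken from a RefSeq gene table of GRCm38.p6, in which 20133 of the 20286 symbols (99.2%) were found. That assembly differs from mm9, so none of its coordinates were used and regions were not assigned to genes.

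Overlaps and tests were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. The overlap code was tested on simulated data, made for the comparison of 5fC with p300 in Tdg -/- ES cells: 0 of 1200 calls differed from a direct search, and 1 of 20 unrelated lists passed the threshold of 0.05 in the shift test. In the class test, a difference of 20 percentage points set in 6000 regions came back as 19.4, and 1 of 20 null differences passed. Alternatives for the regions were an overlap of at least 50% of the region in place of 1 bp (counts), the centre of the region inside the other (tests), the higher-scoring part of each list split at its median score, merging of regions closer than 1 kb, shifts of 20 to 200 kb, classes matched on 10 width classes, and every chromosome name in the files. Alternatives for expression were a pseudocount of 0.1, no FPKM minimum, an FPKM minimum of 5, quantile normalization, and a median change set to 0. Leaving out chromosome 11, 1 score minimum for the 3 5fC lists, subtracting the median change of 25 neighbouring genes, and tests within regions with and without fl/fl 5hmC, with and without chromosome X, were added after seeing the data.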

Results

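Pooled region lists of 5fC, 5hmC and the coactivator p300, a histone acetyltransferase found at enhancers, were compared between Tdg fl/fl and Tdg -/- ES cells, and 5fC and 5hmC also between fl/fl ES cells and fl/fl EB, aggregates in which ES cells begin to differentiate. Behind each list stood 2 libraries for 5fC and 5hmC and 3 for p300. In fl/fl ES cells the lists held 57018 5fC regions over 34.6 Mb, 140943 5hmC regions over 167 Mb and 32160 p300 regions over 30.5 Mb. In Tdg -/- ES cells they held 120052, 174655 and 43345 regions over 111, 229 and 41.2 Mb. EB had 24731 5fC regions over 19.2 Mb and 101593 5hmC regions over 126 Mb. Median widths were 543, 770 and 721 bp for 5fC in fl/fl ES cells, Tdg -/- ES cells and EB, and lay between 818 and 1056 bp for the other lists. Region numbers also depend on depth, which is unknown, and no list has a replicate to set it against.

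The first comparison asked where 5fC gathers when it is no longer excised. Most 5fC regions of Tdg -/- ES cells were gained: 73702 of 120051 (61.4%, 95% interval 61.1 to 61.7) had no counterpart in fl/fl cells. Only 7577 of the 57016 fl/fl regions (13.3%, 13.0 to 13.6) were lost. The gained regions with the highest scores lay at 59061612 to 59063974 on chromosome 11 (score 3210), 43228651 to 43232343 on chromosome 10 (score 3158) and 123097471 to 123099597 on chromosome 8 (score 3153), all in mm9. Gained regions were narrower than kept ones, with a median of 709 against 919 bp. The lost regions had low scores, with a median of 73.2, and the highest reached 352.71 at 4289456 to 4290017 on chromosome 8. Chromosome 11 stood apart, with 4.03 times as many 5fC regions in Tdg -/- as in fl/fl cells, where the ratio lay between 1.86 and 2.35 on the other 18 autosomes. With the higher-scoring part of each list alone, 37415 regions were gained and 4774 lost. The fl/fl list was filtered more strictly, which raises the number gained. With its score minimum applied to the 5fC lists, chosen after seeing the data, 59843 were gained and 9450 lost.

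5hmC changed less. Of the Tdg -/- 5hmC regions, 56405 of 174655 (32.3%, 32.1 to 32.5) were gained, and 17890 of 140943 fl/fl regions (12.7%, 12.5 to 12.9) were lost. The gained region with the highest score (3165) lay at 166929066 to 166932532 on chromosome 2, and the lost one (464.3) at 82105914 to 82107670 on chromosome 10. The ratio of region numbers was 2.21 on chromosome 11 and between 1.15 and 1.33 on the other 18 autosomes. Merging regions closer than 1 kb left 35843 gained regions, and the higher-scoring part of each list gave 29064 gained and 10314 lost.

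p300 regions were gained more often than lost: 18313 of 43345 Tdg -/- regions (42.2%, 41.8 to 42.7) had no fl/fl counterpart, and 6958 of 32160 fl/fl regions (21.6%, 21.2 to 22.1) had none in Tdg -/- cells. The gained region with the highest score (3100) lay at 74839159 to 74840816 on chromosome 8. The lost regions with the highest scores (1292 and 1104) were neighbours on chromosome 11, at 116952237 to 116954621 and 116949558 to 116950544. Among the higher-scoring regions alone, 9130 were gained and 3464 lost. Chromosome 11 stood apart in the other direction than for 5fC: its number of p300 regions in Tdg -/- cells was 0.787 of that in fl/fl cells, while the same ratio lay between 1.34 and 1.48 on the other 18 autosomes.

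**Figure D1:**
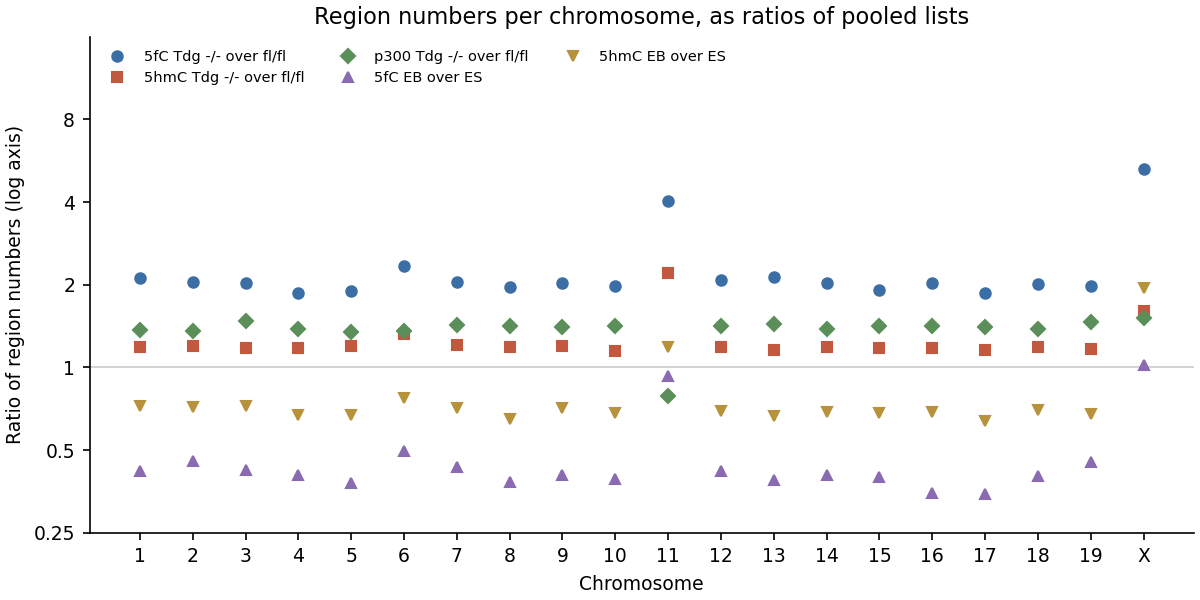
Ratio of the number of regions between 2 pooled lists on each chromosome (log axis), for Tdg -/- over fl/fl ES cells and for EB over ES cells. On chromosome 11 the p300 ratio of Tdg -/- over fl/fl is 0.787 and lies below the other autosomes, while the 5fC ratio of 4.03 lies above them.

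**Figure D2:**
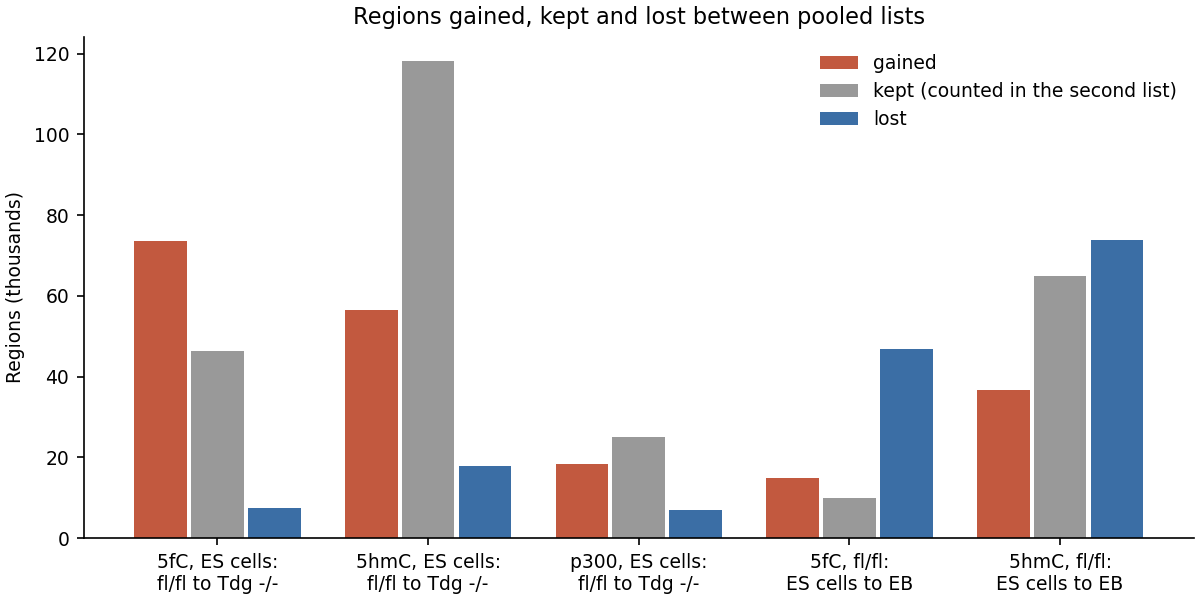
Numbers of regions (in units of 1000, axis from 0) gained, kept and lost in each comparison of 2 pooled lists, with kept regions counted in the Tdg -/- or EB list; each bar is 1 count without replicates. Gained 5fC regions (73702) outnumber kept ones (46349) in Tdg -/- ES cells, while in EB lost 5fC regions (46833) outnumber gained ones (14781).

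5fC regions lay on 5hmC regions in both genotypes. In fl/fl ES cells 89.4% of the 57016 5fC regions overlapped a 5hmC region, 8.54 ± 0.67 times the shifted number (SD of the shifts), and in Tdg -/- ES cells 89.0% of 120051 did, 5.62 ± 0.35 times (p = 1e-03 for each, permutation by circular shifts). Gained 5fC regions had stood on fl/fl 5hmC less often than kept ones. A fl/fl 5hmC region lay at 67.8% of gained and 93.6% of kept 5fC regions, a difference of -25.0 ± 1.11 percentage points (SE over chromosomes) with this sign on 20 of 20 chromosomes (p = 1e-05, sign-flip permutation test). Kept regions overlap fl/fl 5fC by definition, which itself lay on fl/fl 5hmC, so a higher share for them was largely built in. They also had higher scores, with a median of 225.9 against 91.5. A Tdg -/- 5hmC region lay at 84.1% of gained and 96.7% of kept 5fC regions. Against shifts of 20 to 200 kb, which keep the neighbourhood of each region, the folds over 5hmC were 3.28 and 2.47, each with a permutation p = 1e-03.

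Fewer 5fC regions lay on p300. In fl/fl ES cells 7.62% of 5fC regions (7.40 to 7.84) overlapped a p300 region, 3.70 ± 0.26 times the shifted number, and in Tdg -/- ES cells 14.8% (14.6 to 15.0) did, 4.56 ± 0.24 times (permutation p = 1e-03 for each). The difference between these folds was not tested. Seen from p300, 12.9% of the 32160 fl/fl regions held 5fC in fl/fl cells and 38.9% of the same regions did in Tdg -/- cells, while their 5hmC went from 34.1% to 40.8%. The lists themselves grew, from 34.6 to 111 Mb for 5fC and from 167 to 229 Mb for 5hmC, which by itself raises such shares. The local shifts gave lower folds over p300, of 1.55 and 2.09, each with a permutation p = 1e-03.

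A further comparison asked whether p300 regions that came or went with the deletion were those at which 5fC was gained. Gained 5fC lay at 23.6% of gained and 23.6% of kept p300 regions, a difference of 0.36 ± 0.41 percentage points that did not pass the test (p = 0.38, sign-flip permutation test, 12 of 20 chromosomes). This comparison depends on the overlap rule: the difference was 4.40 points where the centre of the p300 region had to lie in 5fC, 3.85 with classes matched on width, and -1.16 after merging of close regions. The 5hmC of the classes also differed, with a fl/fl 5hmC region at 43.4% of gained and 32.8% of kept p300 regions. Gained 5fC leaves out the 5fC regions kept from fl/fl cells, and fl/fl 5fC lay at 18.9% of gained and 11.9% of kept p300 regions. All Tdg -/- 5fC regions together lay at 43.4% of gained and 36.0% of kept p300 regions, a difference that was not tested. In tests chosen after seeing the data, gained 5fC lay at 36.0% of gained and 42.0% of kept p300 regions with fl/fl 5hmC, a difference of -4.97 ± 0.96 points on 19 of 20 chromosomes (permutation p = 1e-04). Among those without it, the shares were 14.1% and 14.6%, a difference of -0.0915 ± 0.45 points that did not pass (permutation p = 0.84). Lost p300 regions did carry gained 5fC more often, at 32.2% (31.1 to 33.3) against 22.9% (22.4 to 23.4) of kept ones. The mean difference over chromosomes was 7.33 ± 0.84 points, with this sign on 19 of 20 (permutation p = 2e-05). It was 4.36 after merging of close regions. A fl/fl 5hmC region lay at 43.8% of lost and 31.4% of kept ones. Among those with it, gained 5fC lay at 43.2% of lost and 41.7% of kept, with a mean difference over chromosomes of -1.82 ± 2.29 points (permutation p = 0.56), or 0.188 ± 1.16 without chromosome X, which held 1 lost and 5 kept regions. Among those without it, the shares were 23.7% and 14.3%, with a mean difference over chromosomes of 6.99 ± 1.06 points (permutation p = 1e-05). These tests, too, were chosen after seeing the data. In the opposite view, a fl/fl p300 region lay at 11.3% of gained and 10.4% of kept 5fC regions (0.85 ± 0.18 points, permutation p = 2e-04, 16 of 20 chromosomes), and this size depends on the setting: it was 3.85 with classes matched on width, 2.16 with the centre inside, 1.75 with the higher-scoring part of each list and 1.31 with 1 score minimum, and after merging the sign turned, to -3.04 points.

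**Figure D3:**
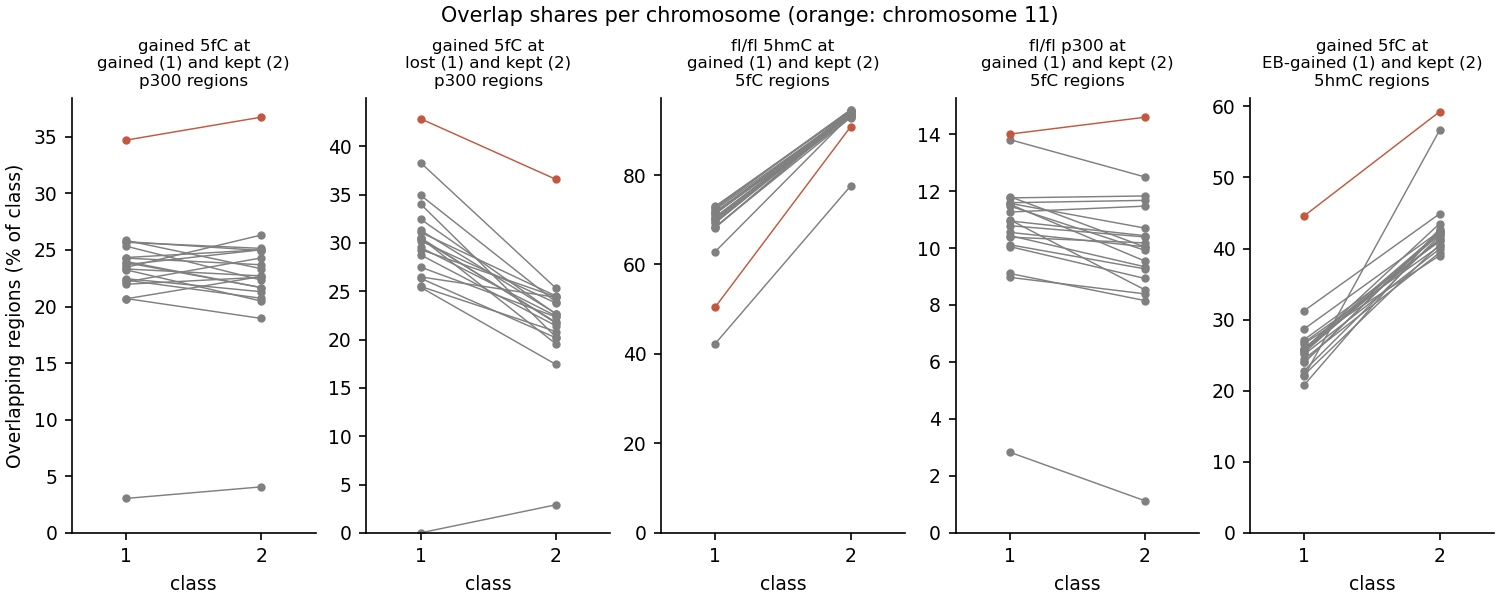
Share of regions (percent, from 0) in class 1 and class 2 that overlap the named mark, with 1 line for each of the 20 chromosomes and chromosome 11 in orange. The lines are close to level for gained against kept p300 regions (23.6% in both), and fall on 19 of 20 chromosomes from lost to kept p300 regions (32.2% and 22.9%).

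EB were compared with ES cells, both Tdg fl/fl, for the marks during differentiation. EB kept few of the ES 5fC regions: 46833 of 57016 (82.1%, 81.8 to 82.5) were lost, and 14781 of the 24727 EB regions (59.8%, 59.2 to 60.4) were gained. 5hmC moved in the same direction to a lesser degree, with 73895 of 140943 ES regions (52.4%, 52.2 to 52.7) lost and 36756 of 101593 EB regions (36.2%, 35.9 to 36.5) gained. The highest score among gained EB 5fC regions (659.82) stood at 98504898 to 98505520 on chromosome 2, and among lost ones (1756) at 168579638 to 168582466 on the same chromosome. Whether either is a region prone to false signal was not checked. For 5hmC, the highest scores stood at 91030263 to 91031925 on chromosome 7 (1672, gained) and at 125093399 to 125097113 on chromosome 8 (3110, lost). With the score minimum of the ES list applied to the 3 5fC lists, chosen after seeing the data, 9740 EB regions were gained, and the higher-scoring part of each list gave 8577 gained and 24672 lost 5fC regions, and 23704 gained and 42952 lost 5hmC regions. Merging left 48991 lost 5hmC regions.

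Of EB 5fC regions, 77.0% (76.5 to 77.5) lay on EB 5hmC, 8.89 ± 0.56 times the shifted number (permutation p = 1e-03), and 4.01 times the number after local shifts. Of the 5fC regions that EB gained, 10256 of 14781 (69.4%, 68.6 to 70.1) overlapped a 5fC region gained in Tdg -/- ES cells, 13.7 ± 0.97 times the shifted number (permutation p = 1e-03), or 6.28 times after local shifts. Both classes were defined against the same fl/fl list. Over 130584 merged regions of the 3 lists, 9949 of 13749 EB-gained regions (72.4%) were gained in Tdg -/- cells. In 100 simulations of unchanged lists that detect regions independently, this share was 91.3% ± 0.24 (SD). With independent detection, this simulated share equals the part of the merged regions found in the Tdg -/- list, whatever the fl/fl list holds. It was thus set by list size and cannot show what the shared fl/fl list adds to the overlap. The fold over the shifts, too, does not separate the shared definition from a gain of 5fC at the same regions in EB and Tdg -/- cells. 5hmC regions gained in EB held gained 5fC of Tdg -/- ES cells at 27.8%, against 42.7% of 5hmC regions kept from ES cells. The mean difference over chromosomes was -17.0 ± 1.06 points, with this sign on 20 of 20 (p = 1e-05, sign-flip permutation test). These gained regions were narrower, with a median of 905 against 1176 bp, and with classes matched on width the difference was -8.83 ± 1.04 points (permutation p = 1e-05). They also lack fl/fl ES 5hmC by definition, and most 5fC regions of ES cells lay on ES 5hmC. All Tdg -/- 5fC regions together lay at 31.1% of EB-gained and 79.3% of kept 5hmC regions. A lower share was thus largely built in, and nothing about EB is read from this test.

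Expression differed little between the genotypes. Tdg, the deleted gene, stood at 22.1 FPKM in fl/fl and 9.48 FPKM in Tdg -/- ES cells, so that 42.9% of its FPKM value remained; which part of the gene was deleted is not given in the sources used here. Of 12053 measured genes, 22 were at least 2-fold higher and 21 at least 2-fold lower in Tdg -/- cells, and 96.5% changed by less than 0.5 on the log2 scale. Across genes, which are not independent replicates, Pearson's r was 0.992. These counts depend on the pseudocount and the minimum: 58 and 52 genes passed with a pseudocount of 0.1, and 11 and 11 with a minimum of 5 FPKM. Without chromosome 11, an alternative chosen after seeing the data, 20 genes were higher and 14 lower, which moves the share of higher genes from 51.2% to 58.8%. Each genotype has 1 pooled value per gene, so none of these differences has a replicate check.

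The genes ranked here are those with at least 5 FPKM in either genotype. The highest log2 changes among them belonged to Fabp7, a brain fatty acid binding protein (2.47, from 0.13 to 5.28 FPKM), and Mid1, a ubiquitin ligase gene on chromosome X (2.34, from 2.01 to 14.2 FPKM). Next came the small nucleolar RNA Snord37 (1.53), Chac1, which degrades glutathione (1.48, from 8.06 to 24.2 FPKM), the small Cajal body RNA Scarna2 (1.28) and the imprinted Grb10 (1.20, from 15.9 to 37.7 FPKM). H2-Eb1 of the class II histocompatibility complex (1.18), the stress transcription factor Atf5 (1.12), Mef2b (1.05), the imprinted Zdbf2 (1.04), Gm514 (1.03) and Ebf1 (0.95) followed. Fabp7 started near 0, and its change was 4.54 with a pseudocount of 0.1. The lowest were Usp26, a deubiquitinase gene on chromosome X (-2.52, from 8.36 to 0.63 FPKM, or -3.53 with a pseudocount of 0.1), Plac8 (-1.57), Igfbp4, an insulin-like growth factor binding protein (-1.30), Snord110 (-1.23) and Sirt7, a nuclear deacylase (-1.19). The lactate transporter Slc16a3 (-1.16), Mrpl12 (-1.14), Tdg itself (-1.14), P4hb, a protein disulfide isomerase (-1.12, from 509.8 to 234 FPKM), Dppa3 (-1.09), Arhgdia (-1.05) and the imprinted growth factor gene Igf2 (-0.99) completed them. Of these 12 lower genes, 6 lie on chromosome 11, which as a whole was lower in Tdg -/- cells: its 759 genes with at least 5 FPKM had a median change of -0.24, against medians of -0.04 to -0.002 on the other 19 chromosomes. After subtracting the median change of 25 neighbouring genes, chosen after seeing the data, Sirt7 was at -0.44, Mrpl12 at -0.49, P4hb at -0.42, Arhgdia at -0.35, Slc16a3 at -0.80 and Igfbp4 at -1.03.

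**Figure D4:**
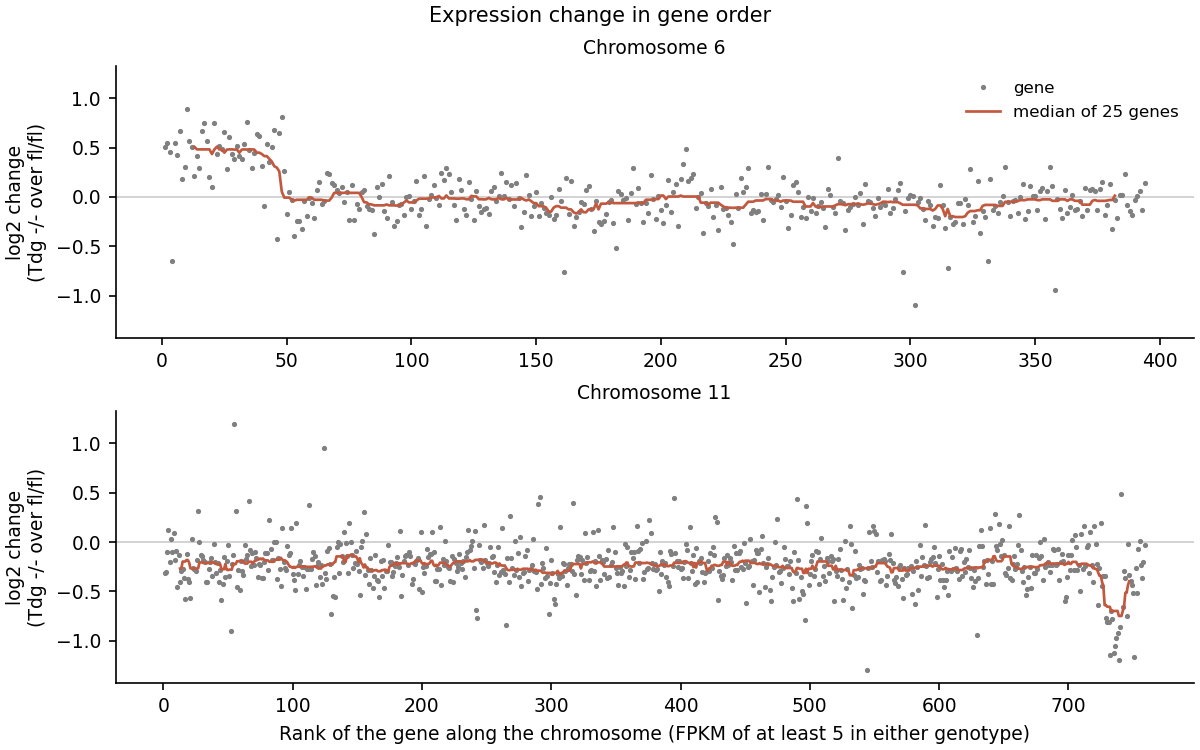
Change of each gene with at least 5 FPKM (grey points, log2 of the FPKM + 1 of Tdg -/- over fl/fl ES cells) against its rank along chromosomes 6 and 11 in GRCm38.p6, with the median of 25 neighbouring genes (orange line). The line lies near 0.5 over the first genes of chromosome 6 and below 0 along the whole of chromosome 11.

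Naive pluripotency genes were slightly higher in Tdg -/- cells, with 10 of 13 above 0, a median of 0.09 (0.15 after quantile normalization) and a percentile of 99.2 among matched random lists. Tcl1 (0.52), Klf5 (0.50) and Tbx3 (0.34) led them, while Dppa3, which protects maternal methylation in the early embryo, was at -1.09. Core pluripotency genes had a median of 0.01 (percentile 92.5, 7 of 12 above 0), with Utf1 at 0.53, Sox2 at 0.24 and Lin28a at -0.20. Primed epiblast genes lay lower, with 7 of 8 below 0, a median of -0.16 (-0.11 with no FPKM minimum) and a percentile of 1.54, led by Lef1 (-0.68) and Otx2 (-0.50), with Fst at 0.50 and Cldn6 at -0.22. Two-cell-like genes had a median of 0.06 (0.02 after quantile normalization, percentile 57.7) over 8 genes with values near the minimum, such as Tdpoz1 (0.32) and Zscan4a (0.14).

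Among lineage genes, the measured endoderm genes were higher, with 6 of 7 above 0, a median of 0.20 (-0.0093 with no FPKM minimum) and a percentile of 99.5. They were mainly basement membrane genes, Lama1 (0.56), Col4a2 (0.53) and Col4a1 (0.32), with Lamb1 at -0.25, and 10 further members, among them Gata6 and Sox17, were under 1 FPKM in both genotypes. The 4 measured mesoderm genes were below 0 (median -0.30, or -0.07 with no FPKM minimum, percentile 0.64), namely Msx2 (-0.37), Gsc (-0.31), Cdx1 (-0.28) and Eomes (-0.01). Neuroectoderm genes had a median of -0.07 (-0.02 with no minimum, percentile 15.8, 6 of 7 below 0), with Neurog1 at -0.46 and Sox1 at 0.19, and trophectoderm genes one of -0.14 (-0.22 with a minimum of 5 FPKM, percentile 2.2, 6 of 8 below 0), with Krt19 at -0.72 and Ascl2 at 0.25. Hox genes were nearly silent, with 5 of 39 measured and a median of -0.03 (0.09 without chromosome 11) and a percentile of 31.3. Markers of fibroblasts or feeder cells, the other cell type such cultures can hold, were lower in 5 of 6 measured genes, with a median of -0.29 (-0.01 with no FPKM minimum and -0.11 with a minimum of 5) and a percentile of 0.15, led by Vim (-0.56), while Fn1 was at 0.34. Col1a1, Col1a2 and Col3a1 were under 1 FPKM in both genotypes.

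Of the 18 lists, the one at the lowest percentile was hypoxia and glycolysis, with 11 of 13 genes below 0, a median of -0.48 and a percentile of 0. Ldha, lactate dehydrogenase, went from 524.8 to 291.5 FPKM (-0.85), Eno1, enolase, from 536.6 to 344 FPKM (-0.64), and Egln3, a prolyl hydroxylase that responds to oxygen, was at -0.67, while the vascular growth factor Vegfa was at 0.65. None of the 13 lies on chromosome 11. Genes of cytosine modification and base excision repair other than Tdg were split 10 to 10 (median -0.03, percentile 55.8), with Lig3 at -0.30, Tet3 at 0.25, Neil2 at 0.23 and Apex1 at -0.21, and enhancer coactivators had a median of 0.01 (percentile 83.7), with Med1, on chromosome 11, at -0.47 and Kdm1a at -0.17. Imprinted genes were split 9 to 9 (median -0.01, percentile 64.6) but held large single changes: H19 (1.27, from 0.31 to 2.18 FPKM) and Grb10 were higher, and Igf2 and Peg10 (-0.65) lower. Germline genes had a median of -0.02 (-0.20 with a minimum of 5 FPKM, percentile 26.2), with Tuba3a at -0.64 and Mael at 0.40. p53 and DNA damage targets had one of -0.09 (-0.05 without chromosome 11, percentile 20.6), with Perp at -0.37 and Eda2r at 0.33, and 3 measured interferon response genes one of -0.15 (-0.02 with no minimum, percentile 11.8), with Bst2 at -0.20. Housekeeping genes had a median of -0.11 (percentile 27.9), which was 0 after quantile normalization, with Ppia, on chromosome 11, at -0.59 and Gapdh at -0.36. After subtracting the median change of neighbouring genes, chosen after seeing the data, some percentiles moved: that of imprinted genes became 1.48, neuroectoderm 2.29, interferon response 3.98, trophectoderm 8.51, cytosine modification and base excision repair 21.5, and Hox genes 61.5.

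**Figure D5:**
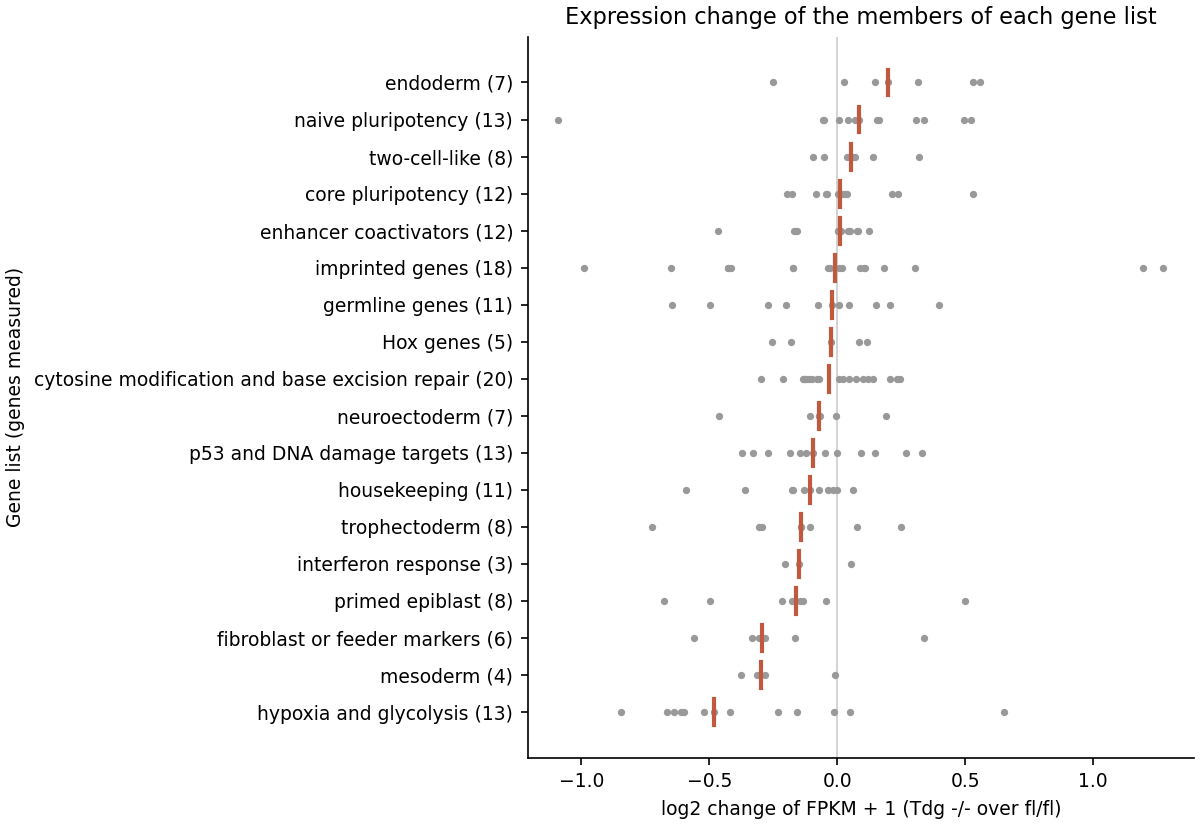
Change of each measured member (grey points) and the median (orange bar) of the 18 gene lists, as log2 of the FPKM + 1 of Tdg -/- over fl/fl ES cells, with the number of genes measured in brackets; each gene has 1 pooled value per genotype. The medians run from -0.48 for hypoxia and glycolysis to 0.20 for endoderm.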

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

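In EB, 4 5fC regions lay on chromosome Y, which the comparisons leave out; this is above the 3 that a count of 0 allows, but the fl/fl and Tdg -/- ES lists held 2 and 1, so that nothing about EB follows from it. Of the tests in this part, those on chromosome 11 were chosen after the results were seen, and the bounds of those within 5hmC classes, and how they were applied, were changed after theirs; leaving out chromosome X was chosen then too.

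Chromosome 11 genes were lower in Tdg -/- ES cells (median -0.24, with 85.9% of 759 genes below the median of all genes). A few strongly changed genes do not account for this, since without genes changed by 0.5 or more the median of the 699 left was -0.23, below that of every other chromosome. A copy number difference of chromosome 11 between the cultures, more copies in fl/fl or fewer in Tdg -/- cells, is a candidate explanation: p300 regions, from other libraries, had a ratio of 0.787 there against at least 1.34 on the other 18 autosomes, and between 0.68 and 0.99 in each of 13 bins of 10 Mb. An effect of Tdg loss on the genes and p300 regions of this chromosome stays open, since the genotype and the culture were not separated by replicates.

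The 5fC and 5hmC lists stood apart on chromosome 11 in the other direction. The ratio of 5fC regions of Tdg -/- over fl/fl ES cells was 4.03 there, above the range of 1.86 to 2.35 on the other 18 autosomes, which argues against the direction seen in RNA and p300 acting alike on the 5fC calls. Too few regions called on chromosome 11 in the fl/fl ES lists, through their DNA or their control library, may account for it: the EB over ES ratio, with the same ES list below the line, was 0.932 against at most 0.498 on the other 18 autosomes, and the 5hmC ratios were 2.21 (at most 1.33 on those autosomes) and 1.18 (at most 0.777). Chromosome X also lay above those autosomes, with EB over ES ratios of 1.02 for 5fC and 1.94 for 5hmC and Tdg -/- over fl/fl ratios of 5.27 and 1.60. Which control each list was called against is not given in the sources used here, and a change of 5fC in these cells stays open.

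Lost p300 regions overlapped gained 5fC more often than kept ones (32.2% against 22.9%). Lower p300 scores of the lost regions, with a median of 70.8 against 125, do not explain it, since classes matched on score differed by 7.78 ± 1.05 points (p = 1e-05, sign-flip permutation test over 20 chromosomes). Called fl/fl 5hmC does not explain it among regions without a fl/fl 5hmC region, at 23.7% of lost and 14.3% of kept. The mean difference over chromosomes was 6.99 ± 1.06 points there (permutation p = 1e-05). 5hmC under the threshold of the calls can lie at such regions, so this test cannot exclude it. A Tdg -/- 5hmC region lay at 54.9% of all lost and 36.9% of all kept p300 regions, and a fl/fl one at 43.8% and 31.4%. Among regions with a fl/fl 5hmC region, gained 5fC lay at 43.2% of lost and 41.7% of kept. The mean difference over chromosomes was -1.82 ± 2.29 points (permutation p = 0.56). Without chromosome X, which held 1 lost and 5 kept regions, it was 0.188 ± 1.16 (permutation p = 0.87). An excess of 3 points was not seen there. 5hmC may account for this, but so may the definition of gained 5fC, which leaves out regions shared with fl/fl 5fC. Among these p300 regions, fl/fl 5fC lay at 38.8% of lost and 32.3% of kept (6.80 ± 1.16 points, permutation p = 3e-05). All Tdg -/- 5fC regions together lay at 52.5% of all lost and 35.2% of all kept p300 regions, which was not tested. Chromosome 11, where the fl/fl ES 5fC and 5hmC lists may hold too few calls, raised the pooled shares given here. Of the 6958 lost regions 5810 lay elsewhere, and on chromosome 11 gained 5fC lay at 42.9% of lost and 36.6% of kept regions. The differences over 20 chromosomes count it once. An effect of 5fC on p300 binding, or of p300 loss on 5fC, was not tested and stays open.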

How the results depend on the processing

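Leaving out chromosome 11, 1 score minimum for the 5fC lists and subtracting the median of neighbouring genes were chosen after seeing the data. No paired analysis was possible because each group has 1 pooled list or value, and for the same reason no replicate was left out; gene features under regions were not run, since the annotation used here is not of mm9. The 6 enrichments over shifted regions kept their direction and side of the threshold in all 42 alternatives, but shifts of 20 to 200 kb lowered their folds to between 1.55 and 6.28. Other settings raised some folds. With the centre inside, Tdg -/- 5fC over 5hmC rose to 8.69 and ES gained 5fC at EB-gained 5fC to 21.5. With the higher-scoring part of each list, EB 5fC over 5hmC rose to 14.5. Of 35 alternatives of the class tests, 31 kept their direction and side of the threshold. Gained 5fC at gained against kept p300 regions, not past the threshold at 0.36 points, passed it with the centre inside (4.40) and matched on width (3.85) and turned after merging (-1.16, permutation p = 0.0082), and fl/fl p300 at gained against kept 5fC regions turned after merging to -3.04 (permutation p = 3e-05); the cause was not tested. Of 68 alternatives of the counts, 51 stayed within 1.5 times. The higher-scoring part of each list, smaller by construction, gave 37415 gained and 4774 lost 5fC, 29064 and 10314 5hmC, and 9130 and 3464 p300 regions in Tdg -/- cells, and 8577 and 24672 5fC and 23704 and 42952 5hmC regions in EB. Merging gave 35843 gained 5hmC regions in Tdg -/- cells and 48991 lost in EB, and 1 score minimum gave 9740 5fC regions gained in EB. Genes at least 2-fold higher and lower numbered 58 and 52 with a pseudocount of 0.1, and 11 and 11 with a minimum of 5 FPKM, which tests fewer genes. Of 107 alternative list medians 102 stayed within the bootstrap interval of the list, which is wide for lists of few genes, and 6, of 4 lists, changed sign: endoderm to -0.0093 without a minimum, when silent members enter, and lists with medians near 0, namely Hox genes to 0.09 with a minimum of 5 FPKM or without chromosome 11 and to 0.07 with neighbours subtracted, germline genes to 0.0036 with neighbours subtracted, and cytosine modification and base excision repair to 0.0081 without chromosome 11. None of the 24 named genes changed sign in 72 alternatives, but 22 values moved by over 0.1, of them 12 with a pseudocount of 0.1, 9 with neighbours subtracted and 1 with quantile normalization. Depth is unknown, and a deeper library gives more regions and higher scores.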

Other observations

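The tests in this part were chosen after the results were seen, and so were the genes named in it. Among the largest changes were Chac1 (1.48) and Atf5 (1.12), with Asns, asparagine synthetase, at the start of chromosome 6 (0.89), all targets of ATF4, a transcription factor of the amino acid and stress response. A list of 30 other ATF4 and amino acid response genes was drawn up after these had been seen, and left out Gpt2 and Pck2, which had also been seen to be higher, so that it is not independent of the pattern. In it, 29 were above 0, with a median of 0.36, which lay at the percentile of 100 among 10000 matched random lists and stayed at 100 after subtracting the median of neighbouring genes. Vldlr was at 0.77, Cth, which makes cysteine, at 0.61, Trib3 at 0.60 and Atf3 at 0.55. A higher amino acid response in the Tdg -/- culture is a hypothesis in line with this value, and whether it belongs to the genotype or to the state of the cultures on the day of harvest was not separated by replicates.

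Genes at the start of chromosome 6 were higher together. From Ccdc132 to Mkln1, 45 of 48 neighbouring genes with at least 5 FPKM were above 0, with a median of 0.49 against -0.06 on the rest of the chromosome. The window of 25 genes from Asns to Calu had a median of 0.51, where the highest window on chromosomes other than 6 and 11 had 0.17. The imprinted Peg10, within this run, was at -0.65. In the first 30 Mb of chromosome 6 (mm9), the ratio of Tdg -/- over fl/fl regions was 8.04 for 5fC (99 and 796 regions, against 2.12 on the rest), 3.01 for 5hmC (against 1.22) and 1.402 for p300 (against 1.36). The EB over ES ratios there were 2.39 for 5fC and 1.85 for 5hmC, against 0.42 and 0.71 on the rest. At the end of chromosome 11, 12 neighbouring genes from Ccdc137 to Mafg were lower, with a median of -0.89 against -0.24 on the rest of that chromosome.

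fl/fl p300 lay at 24.9% of the 5fC regions gained in EB and 14.5% of those kept from ES cells, a difference of 10.5 ± 0.50 points on 20 of 20 chromosomes (p = 1e-05, sign-flip permutation test), and of 11.2 ± 0.59 with the classes matched on score. fl/fl 5fC lay at 18.9% of the p300 regions gained in Tdg -/- cells against 11.9% of kept ones, a difference of 6.65 ± 0.47 points on 20 of 20 chromosomes (p = 1e-05), and of 4.94 ± 0.63 matched on score. It also lay at 18.2% of lost against 11.4% of kept p300 regions, a difference of 6.67 ± 0.64 points (permutation p = 2e-05, 19 of 20 chromosomes), and of 4.31 ± 1.04 matched on score (permutation p = 6e-05, 17 of 20 chromosomes). These classes also differed in fl/fl 5hmC, at 43.4% of gained and 32.8% of kept and at 43.8% of lost and 31.4% of kept regions. Among p300 regions with fl/fl 5hmC the differences in fl/fl 5fC were 8.20 ± 0.82 points for gained (permutation p = 1e-05) and 6.80 ± 1.16 for lost ones (permutation p = 3e-05). Among those without it, few held fl/fl 5fC, at 2.58% of gained against 1.88% of kept (0.692 ± 0.13 points, permutation p = 1e-04) and 2.10% of lost against 1.88% of kept (0.110 ± 0.23 points, permutation p = 0.63, not past the threshold). On chromosome X, 5fC regions went from 104 in fl/fl to 548 in Tdg -/- ES cells, a ratio of 5.27, but other ratios stood apart there too. EB over ES was 1.02 for 5fC, against 0.346 to 0.498 on the 18 autosomes other than chromosome 11, and 1.94 for 5hmC, and Tdg -/- over fl/fl was 1.60 for 5hmC, so that 5.27 is not read as an effect of Tdg.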
